A study of Mus musculus with 2 samples.

How the data were processed

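RNA from the livers of wild-type and Pnpla8 knockout mice was hybridised to 2 one-colour Agilent mouse arrays, 1 per genotype. Per the labels' protocols, total RNA was purified on RNeasy columns, its quality was assessed on a Bioanalyzer, and 200 ng was amplified and labelled with Cy3 by the Low Input Quick Amp kit. Samples were grouped by the genotype in the labels. Spot intensity was extracted by the authors with Agilent Feature Extraction 11.5.1.1, per the submitters' processing notes, and the deposited scanner files give each spot's intensity on a linear scale, raw and after background subtraction. The deposited value table held intensity too: each column was that array's processed signal divided by a constant, 1207 for the wild type and 1019 for the knockout. Its column medians were 0.0800 and 0.0763. The table is linear and not centred per gene, and whether the authors chose the constant as a 75th percentile is not given in the sources used here. No per-sample column was left unused (0 others).

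From the scanner files, log2 of the processed signal was taken and each array's 75th percentile over non-control spots was subtracted. Control spots were left out, as were spots with a non-uniformity or population outlier mark (896 on the wild-type array and 913 on the knockout array). Spots of 1 probe were averaged on the log2 scale. A probe was measured when it was well above background on both arrays, and a gene's ratio was the median over its measured probes. A gene well above background on 1 array only was given a bound: the bright value against the higher of the dim probe's own value and the lowest value that was well above background on the dim array. The knockout array's lowest such signal was 17.9 and the wild-type array's 14.7, so a bound on a gene lower in the knockout is the smaller for the same bright signal. Scaling does not remove the floor: at the negative controls the scaled signal was 0.53 higher on the log2 scale on the knockout array, so ratios of the dimmest genes are drawn upward. Medians over deciles of mean signal ran from 0.00 to 0.11.

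Array gene names can be old. Of 39429 probes, 28330 were named through their accession and 2378 through their name in the RefSeq gene table of assembly GRCm38.p6, and 8721 kept the file's name. The table served for names alone, because 8.76% of 28530 probe coordinates lay inside their gene's interval in that assembly; the build of the array files is not given in the sources used here.

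With 1 array per group no test across samples was made, no replicate could be left out and no p-value is given. Genes were counted at a fixed ratio of at least 2-fold. For each of 40 gene lists, the median log2 ratio of its measured genes was placed among the medians of 10000 random lists of the same size drawn from 20 bins of mean signal, where at least 5 members were measured. In 13 lists some members had bounds, and setting these at their bound moved no list median by more than 0.09 and changed the sign of 1, the ATF4 list.

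Named genes followed a rule fixed before the data were examined: Pnpla8 and its list; the 12 highest and 12 lowest measured genes with an approved symbol, all probes on the same side and at least median signal on the brighter array; the 3 highest and 3 lowest bounds; and in each list up to 4 members with the largest absolute ratio. An approved symbol was taken as one held in the RefSeq table that was not a predicted-gene, clone or accession-like name. Of the genes it selects, 1 is not reported here. The alternatives were other scalings (median, quantile, loess with a span of 0.3, none), a normexp background with an offset of 50, the deposited value table, other probe filters and summaries, other fold thresholds, and other ways to draw or summarise lists. Scaling to the 8 E1A spike-in controls well above background on every spot was added after the data were seen. The arrays were read with pandas 2.3.3 and numpy 2.4.6 in Python 3.11.15, loess came from statsmodels 0.14.6 and normexp from limma 3.58.1 in R 4.3.3.

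The steps were tested on simulated data with the probe spread of these arrays. In the simulated comparison of 19394 genes, 50 of 50 genes planted at 3-fold were counted at 2-fold or more, as were 50 of 50 at 4-fold and 50 of 50 at 8-fold, and 0 of 50 at 1.5-fold. Of 400 random lists without a shift, 18 lay outside the middle 95%, and of 50 lists shifted by 0.3 on the log2 scale, 50 did. The lists without a shift were drawn from the same simulated genes as the random lists, so a share near 5% was fixed in advance. It does not cover lists whose members vary together. All 100 genes switched off on 1 array received a bound within the true fold. The simulated dim signal and the floor both lay above the true value, so that outcome was fixed in advance and does not test the bounds. The probe spread is technical, so the simulation says nothing of differences between animals. It is also narrower than the spread of log2 ratios over all measured genes (SD 0.39), so recovery of genes and lists may be lower in these data.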

Results

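Gene expression was measured in mouse liver on 2 one-colour arrays, 1 for wild-type animals and 1 for animals lacking Pnpla8, which encodes a calcium-independent phospholipase A2 that cleaves fatty acids from membrane phospholipids. The strain was C57BL/6N. Each array held RNA pooled in equal amounts from 5 animals per the series design text, which gives the age as 8 weeks, while the sample labels give 6 weeks; which is right was not settled by the sources used here. The series title places the comparison in a study of how hepatic phosphatidylcholine breakdown yields choline, whose methyl groups can enter the methionine cycle. With 1 array per genotype no difference had a replicate check, no test across samples was possible, and genotype, pool and array position could not be separated. Genes are therefore described as higher or lower in the knockout pool by a fixed size of at least 2-fold, and the number of arrays limits the precision.

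On the wild-type array 30141 of 43020 non-control spots (70.1%) were well above background, and on the knockout array 28212 (65.6%). The 75th percentile of the processed signal was 1207 on the wild-type array and 1018 on the knockout array. No non-control spot was saturated on either array. Of the genes on the array, 19394 were measured on both, and their median log2 ratio of knockout over wild type was 0.04. The ratio of a probe spotted 10 times had a median SD of 0.05 on the log2 scale between its spots (298 probes). Different probes of a gene had a median SD of 0.10 (4045 genes). Both describe technical spread within these arrays and not the spread between animals or pools.

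Pnpla8 itself was well above background in the wild-type pool and not well above background in the knockout pool. Its single probe, A_55_P2114347, read a processed signal of 144.5 in the wild type and 4.45 in the knockout, which made it at least 6.81-fold lower in the knockout pool. The bound sets the wild-type signal against the lowest signal that was well above background on the knockout array. The probe was designed on transcript NM_026164, has the sequence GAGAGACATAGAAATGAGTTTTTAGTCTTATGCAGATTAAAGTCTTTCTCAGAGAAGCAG and is placed by the array file on chromosome 12 from 45414232 to 45414291, in a genome build the file does not name. The part of the gene removed in the knockout is not given in the sources used here, so whether the probe lies inside it is unknown and a probe outside it would not check the labels. With the normexp background the bound was a log2 ratio of -1.10.

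Among the other members of the patatin-like phospholipase list, Pnpla3, a lipid droplet lipase, was 7.91-fold lower in the knockout pool. Pla2g4a, cytosolic phospholipase A2, was 2.28-fold lower, a value short of 2-fold with the normexp background. Pnpla5 was well above background only in the wild type and at least 3.66-fold lower, with a log2 bound of -0.39 under normexp. The remaining measured members were within 2-fold. Pnpla7 had a log2 ratio of -0.21, Pnpla6 -0.06, Pnpla1 0.05 and Pnpla2, adipose triglyceride lipase, 0.69. Pla2g6 had -0.30, Pla2g15 -0.26, Pla2g12b -0.03, Plaat3 0.00, Abhd5 0.04, Pla2g7 0.04 and Pla2g12a 0.46. The median of the 13 measured members was -0.03, at percentile 18.3 of random lists of the same size matched on mean expression; by its mean, -0.29, the list lay outside the random range.

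Over all measured genes, 253 were at least 2-fold higher and 359 at least 2-fold lower in the knockout pool. Of the genes past 2-fold, 41.3% were on the higher side. That split depended on the scaling: without scaling 114 were higher and 746 lower, with the E1A spike-in controls as the scale 142 were higher and 576 lower, and with the normexp background 131 were higher and 124 lower. At 4-fold the main counts were 24 higher and 14 lower. Of 61 genes past 2-fold with several measured probes, 58 had all probes on the same side and 39 had every probe at 2-fold or more. A further 269 genes were well above background only in the knockout pool and 1623 only in the wild type, where more spots passed that limit. The bound reached 2-fold for 179 of the former and 156 of the latter. These 2 counts cannot be set against each other, because the floors differed. The lowest scaled log2 signal well above background was -5.83 on the knockout array and -6.36 on the wild-type array. A bound therefore reached 2-fold more easily for genes found only in the knockout pool.

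Among genes that met the naming rule, all of at least median signal on the brighter array, Sult1e1, the estrogen sulfotransferase, was the highest in the knockout pool at 32.4-fold. It was followed by the cyclic nucleotide phosphodiesterase Pde5a (5.64-fold), the metallothionein Mt2 (4.41-fold), the mTORC1 inhibitor Ddit4 (4.38-fold), the lipid droplet coat gene Plin4 (4.29-fold), Pde6c (4.12-fold), Raet1e (4.04-fold) and the nicotinamide methyltransferase Nnmt (4.03-fold). Erdr1 (3.95-fold), Sult2a4 (3.61-fold), Lrtm1 (3.52-fold) and Mt1 (3.39-fold) completed the 12 highest. The lowest was the pseudogene Serpina4-ps1, 22.3-fold lower with both of its probes. Fgf21, a fasting- and stress-responsive hormone, had a log2 ratio of -3.58. The steroid dehydrogenase Hsd3b5 was 10.6-fold lower, Ly6d 9.72-fold, the calcium pump gene Atp2b2 7.96-fold and the organic anion transporter Slco1a1 6.57-fold. Prok1 was 6.05-fold lower, Cgref1 4.62-fold, Dntt 4.54-fold, the taurine synthesis enzyme Csad 4.29-fold, the Cdk1-inhibiting kinase Pkmyt1 3.99-fold and the carbonyl reductase Cbr3 3.97-fold. Probes for the Sult2a, Raet1, metallothionein and Hsd3b families can also bind near-identical copies. Among genes measured on 1 array only, Chil1 had a log2 bound of 3.33, Olfr446 was at least 6.72-fold and Lrtm2 at least 6.42-fold higher in the knockout, while Dmbt1 was at least 13.3-fold, Fut1 at least 10.7-fold and Vipr2 at least 8.28-fold lower. With the normexp background these log2 bounds shrank to 1.28 for Chil1, 1.18 for Olfr446, 1.19 for Lrtm2, -1.57 for Dmbt1, -1.65 for Fut1 and -1.45 for Vipr2.

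**Figure D1:**
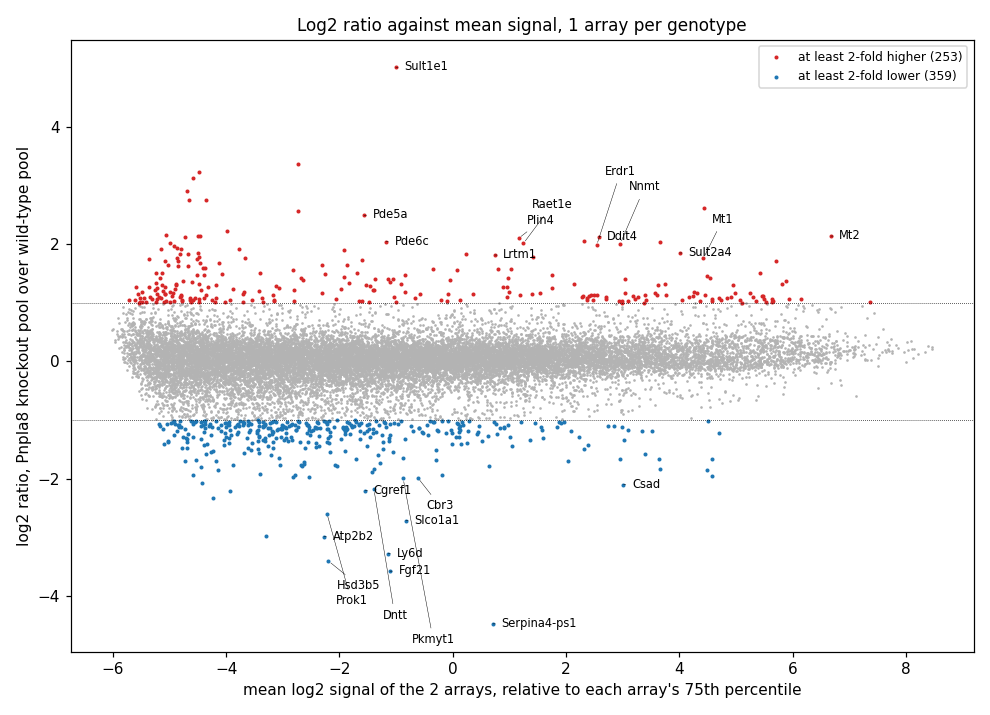
Log2 ratio of the knockout pool over the wild-type pool (vertical axis) against the mean log2 signal of both arrays relative to each array's 75th percentile (horizontal axis), with 1 point per measured gene. The 253 genes at least 2-fold higher are red, the 359 at least 2-fold lower are blue, and dotted lines mark 2-fold. Labels name the 12 highest and 12 lowest genes, from Sult1e1 at 5.02 to Serpina4-ps1 at -4.48. Only genes with an approved symbol, all probes on the same side and at least median signal on the brighter array were labelled.

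Of 40 gene lists chosen before the data were examined, 39 had at least 5 measured members. The medians of 23 lay outside the middle 95% of 10000 random lists, where 1.95 would if list members varied independently. Of these, 9 were higher and 14 lower. The percentiles describe these arrays and carry no p-value, because genes are not replicates. Members of a list can vary together and some lists share genes, so the excess over 1.95 does not measure an effect of genotype. Without scaling every list median shifted by -0.25 together with all genes, which left the respiratory chain list at 0.029 and the xenobiotic list at 0.043; with quantile scaling these were 0.14 and 0.16. Without scaling, Cth, Gpcpd1, Ppargc1a, Etnppl, Slco1a4, Ciart, Cyp2b13, Krt23 and Btg2 fell short of 2-fold, and so did Gpcpd1, Ppargc1a, Etnppl, Slco1a4 and Ciart with the spike-ins. With the normexp background Ppargc1a, Ciart, Slc51b, Cela1, Igf2bp3, H19 and Mest did. Mest also fell short of 2-fold without the filter on dim probes.

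The choline oxidation, methionine cycle and transsulfuration genes were higher in the knockout pool. Their median log2 ratio was 0.42 over 23 measured genes, at percentile 99.99, with 20 above 0 and 3 at least 2-fold higher. These were Nnmt, Cth (cystathionine gamma-lyase, 2.27-fold) and Bhmt (betaine-homocysteine methyltransferase, 2.03-fold). Bhmt fell short of 2-fold without scaling, with quantile, loess, normexp or spike-in scaling and by its brightest probe. Ahcy had a log2 ratio of 0.94. The phosphatidylcholine synthesis, remodelling and choline release list had a median of 0.08 at percentile 64.9. Within it Gpcpd1, a glycerophosphocholine phosphodiesterase, was 2.21-fold higher, and Gdpd1 (-0.59), Gde1 (0.55) and Etnk2 (0.71) were within 2-fold.

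Amino acid breakdown and urea cycle genes had the highest median of any list, 0.82, above all 10000 random lists. All 25 measured members were above 0 and 7 were at least 2-fold higher, among them the transaminase Got1 (3.30-fold), serine dehydratase Sds (2.75-fold), tyrosine aminotransferase Tat (log2 ratio 1.32) and ornithine aminotransferase Oat (2.47-fold). Gluconeogenesis, glycolysis and glycogen genes had a median of 0.35, also above all random lists, with the glycogen-targeting subunit Ppp1r3g (2.78-fold), Igfbp1 (2.58-fold) and the coactivator Ppargc1a (2.12-fold) higher and Ppp1r3b at 0.66. Periportal hepatocyte genes had a median of 0.60, above all random lists, with Etnppl 2.20-fold and Hal 2.003-fold higher, and Cps1 at 0.99. The pericentral list had 0.18 at percentile 92.8. Its Slc1a2 had 0.57, Lhpp 0.68 and Tbx3 -0.59, and Oat belongs to it too. Hal fell short of 2-fold without scaling, with loess, quantile, normexp or spike-in scaling.

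Lipid synthesis genes were lower. The fatty acid synthesis list had a median of -0.55, below all 10000 random lists, with 18 of 22 genes below 0. G6pdx, which supplies NADPH, was 3.43-fold lower and fatty acid synthase, Fasn, 2.46-fold lower, while Elovl6 had -0.97 and Me1 -0.78. The cholesterol synthesis list had -0.21, below all random lists, with squalene epoxidase, Sqle, 2.28-fold lower and Mvd (-0.98), Cyp51 (-0.89) and Hmgcs1 (-0.88) within 2-fold. Fatty acid oxidation genes had 0.17 at percentile 93.0, with Angptl4 at 0.64, Cyp4a10 at 0.90 and Cyp4a31 at 0.92 beside the lower Fgf21. Lipid droplet, triglyceride and lipoprotein genes had 0.13 at percentile 85.5, with the uncoupling protein gene Ucp2 2.28-fold lower, Pltp at -0.95 and Cd36 at 0.92. Bile acid genes had 0.14 at percentile 82.6. The transporter Slco1a4 was 2.18-fold higher and Slc51b 2.41-fold lower, and Cyp7a1, the rate-limiting enzyme of bile acid synthesis, had 0.89 and Cyp8b1 0.86.

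Respiratory chain subunits were higher by a small amount, with a median of 0.27 at percentile 99.7. All 33 were above 0 and none reached 2-fold, with Sdhb highest at 0.66, then Cyc1 (0.49), Uqcrc1 (0.40) and Atp5c1 (0.39). The cardiolipin and mitochondrial dynamics list had 0.18 at percentile 97.6, a median that was -0.066 without scaling and that lay inside the random range under 4 other settings. Its Mfn2 had 0.47, Lclat1 0.47, Mfn1 0.43 and Tamm41 0.38. Xenobiotic receptor targets had 0.29 at percentile 99.8, with the sulfotransferase Sult1d1 2.41-fold higher and Nr1i3 (0.64), Cyp3a25 (0.62) and Por (0.56) within 2-fold.

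Of 6 lists of stress genes, 3 had medians below the random range and 3 had medians inside it. The endoplasmic reticulum unfolded protein response list had a median of -0.40, below all random lists, with Derl3 3.19-fold and Sdf2l1 2.15-fold lower and Creld2 (-0.90) and Ero1b (-0.86) within 2-fold. The ATF4 list went both ways. Its median was 0.04 at percentile 43.6 and its mean -0.24, which lay outside the random range, with Psat1 (3.91-fold) and Asns (3.27-fold) lower beside Fgf21, and Ddit4 higher. The NRF2 and glutathione list had -0.16, below all random lists, with Cbr3 lower, the glutathione transferase gene Gsta2 2.68-fold higher, Gstm4 at -0.47 and Srxn1 at -0.47. The p53 list had -0.19 at percentile 0.050, yet Cdkn1a, the cell cycle inhibitor p21, was 3.31-fold and Btg2 2.23-fold higher, with Trp53inp1 at 0.91 and Gtse1 at -0.80. Heat shock genes had a median of 0.00 at percentile 13.3 (outside the random range when spots with an outlier mark were kept) and a mean of -0.08, with Hsp90aa1 at -0.83, Hsph1 at -0.57, Hspa1a at -0.35 and Hspb8 at 0.37. The autophagy and lysosome list had 0.11 at percentile 75.5, with Bnip3 (0.61), Map1lc3b (0.56), Ctsl (0.52) and Atg7 (0.36). The p53 median was -0.11 with normexp, and the list was inside the random range when its mean replaced its median.

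Immune cell and proliferation genes were lower. The Kupffer cell and macrophage list had a median of -0.91, below all 10000 random lists, with none of 21 genes above 0 and 9 at least 2-fold lower. Among these were the chemokine Ccl2 (2.74-fold), the scavenger receptor Marco (2.53-fold), Cd5l (2.33-fold) and the macrophage marker Adgre1 (2.24-fold). The lymphocyte and NK cell list had -0.89, below all random lists, with 7 of 20 genes at least 2-fold lower, such as the class II invariant chain Cd74 (2.68-fold), Cd3d (2.55-fold), Ms4a1 (2.53-fold) and Ccl5 (2.28-fold). With the normexp background its median was -0.47, and among probes above the median signal on both arrays, where 5 of its genes remained, -0.14, inside the random range. Interferon response genes had -0.59, below all random lists, with none of 31 above 0 and Igtp (2.27-fold), Mx1 (2.25-fold), Ifi47 (2.18-fold) and Irf7 (2.12-fold) lower. The cell cycle list had the lowest median, -1.03, below all random lists, with 14 of 26 genes at least 2-fold lower, including the replication helicase genes Mcm5 (3.31-fold) and Mcm2 (2.73-fold), Top2a (2.88-fold) and Pbk (2.51-fold). Cd3d, Ms4a1, Mx1, Mcm2, Top2a and Pbk fell short of 2-fold with the normexp background.

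Markers of other liver cells were measured beside these. Stellate cell, fibroblast and matrix genes had a median of -0.41, below all random lists, with Acta2 2.02-fold lower (short of 2-fold with normexp, quantile or median scaling), Timp1 at -0.91 and Ccn2 at 0.84. Endothelial markers had -0.16 at percentile 0.19, inside the random range by the mean, with Lyve1 (-0.66), Cdh5 (-0.44), Tek (-0.29) and Gpr182 (-0.26). Cholangiocyte markers had 0.12 at percentile 84.1, with Krt23 2.25-fold higher, Cldn4 at 0.48, Cftr at 0.34 and Prom1 at 0.32. Neutrophil markers had -0.10 at percentile 6.37, with S100a8 (3.37-fold) and S100a9 (3.13-fold) lower, Retnlg at -0.65 and Lcn2 at 0.97. Erythroid markers had 0.01 at percentile 43.1, with Hbb-b1 at -0.05, Hba-a1 at 0.05, Ermap at 0.16 and Klf1 at 0.86. Markers of pancreas, muscle and fat had a median of 0.14 at percentile 78.0 and a mean of -0.01, with Cela1 2.77-fold lower, Amy2a5 at 0.84, Car3 at 0.47 and Mylpf at 0.38. The acute phase list had 0.15 at percentile 88.3, with Socs3 (2.36-fold) and Saa3 (2.15-fold) lower beside the higher metallothioneins. Eicosanoid genes had -0.06 at percentile 1.89, with Tbxas1 2.31-fold lower and Ptgds (-0.96), Alox5ap (-0.78) and Ptgs1 (-0.66) within 2-fold. That median was 0.020 among probes above the median signal, inside the random range, and the list was inside it too when random lists were not matched on expression.

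Sex-biased genes differed in opposite directions. Male-biased liver genes had a median of -0.24, below all random lists, led by Hsd3b5 and Slco1a1, with C6 at -0.80 and Mup21 at -0.78. Female-biased genes had 0.42, above all random lists, with Sult1e1, Atp6v0d2 (2.83-fold) and Cyp2b13 (2.24-fold) higher and Cyp3a44 2.30-fold lower. Probes of the Mup, Cyp2b and Cyp3a families can bind near-identical copies. Xist, transcribed from the inactive X chromosome, had 0.07 and was well above background in both pools, and no Y-linked probe was well above background in either. The growth hormone axis list had a median of -0.05 at percentile 3.55 and a mean of 0.02, with Cish (-0.85), Socs2 (-0.64) and Bcl6 (0.65) within 2-fold and Igfbp1 higher. The circadian clock list had 0.22 at percentile 99.3, a median that was -0.028 without scaling, with Ciart 2.08-fold higher and Arntl (0.85), Cry1 (0.83) and Usp2 (0.57) within 2-fold. Fetal and perinatal liver genes had -0.17 at percentile 0.95, but the list lay inside the random range without the filter on dim probes (0.095), among probes above the median signal (-0.088) and with the mean of probes per gene (-0.086). Igf2bp3 (2.86-fold), H19 (2.19-fold) and Mest (2.17-fold) were lower and Tff3 2.68-fold higher. Reference genes had 0.12 at percentile 66.9, with Actb at -0.40, Gapdh at 0.39, Pgk1 at 0.37 and Ywhaz at 0.25.

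**Figure D2:**
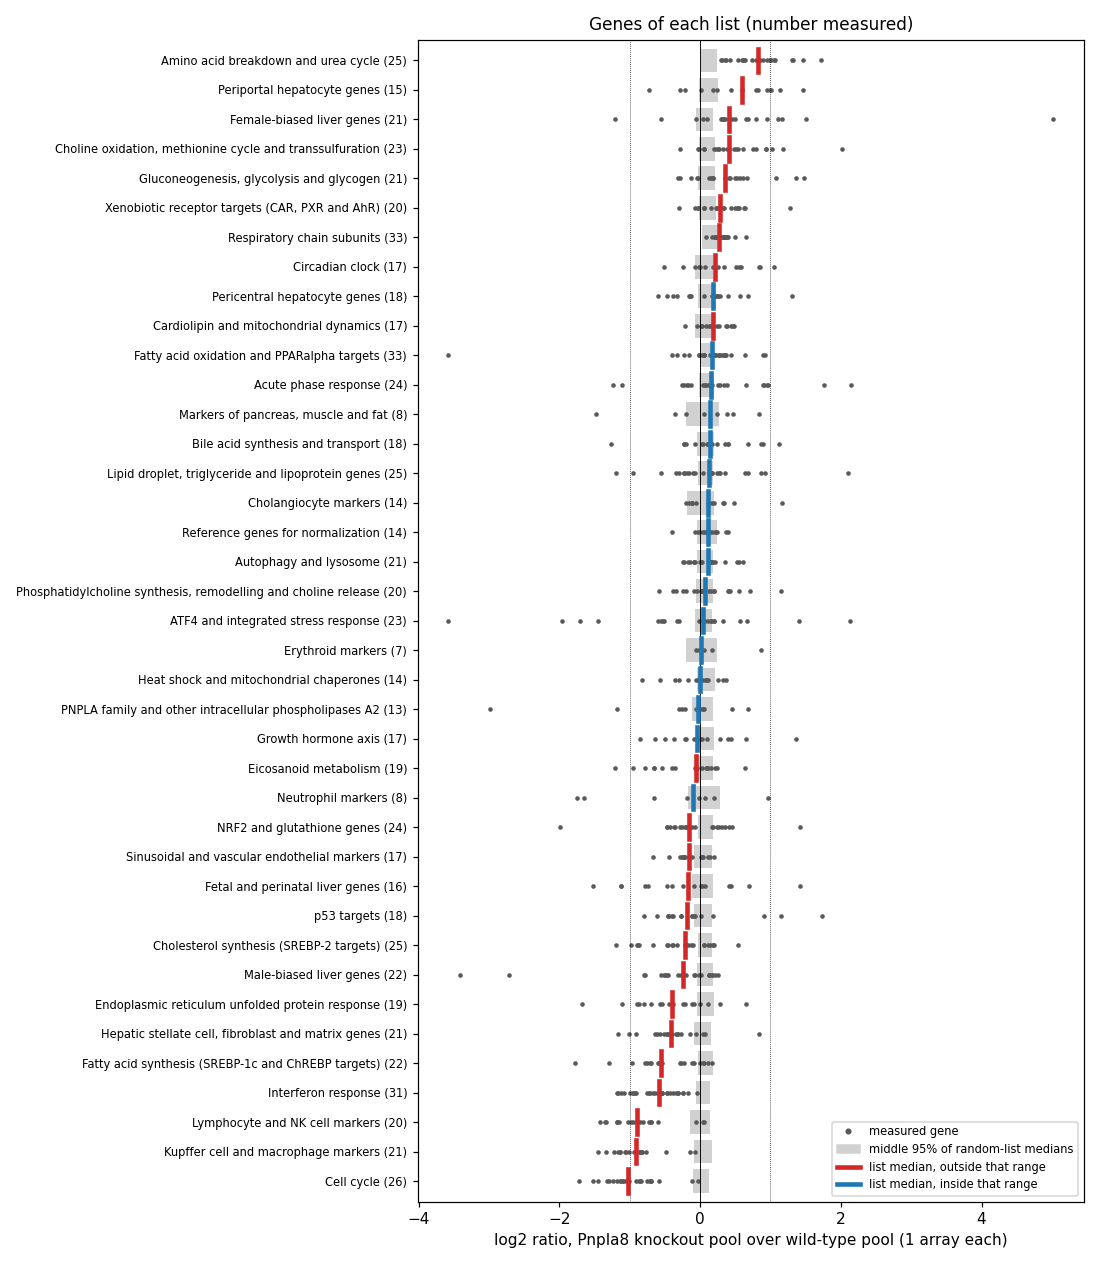
Log2 ratios of the knockout pool over the wild-type pool (horizontal axis) for the measured genes of 39 lists (rows, number measured in parentheses). Points are genes, thick ticks are list medians, grey bars span the middle 95% of medians of 10000 random lists, and dotted lines mark 2-fold; the list medians run from -1.03 for cell cycle to 0.82 for amino acid breakdown, and without scaling those of cardiolipin and circadian clock genes lie below 0.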

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

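Scaling to the E1A spike-ins was chosen after seeing the data; the other settings were fixed before. No paired analysis was possible because each genotype had 1 array, and no array could be left out. Without scaling the median of all genes moved by -0.25 on the log2 scale and with the spike-ins by -0.15; other scalings moved it by less than 0.1. Against 253 genes higher and 359 lower, the counts were 114 and 746 without scaling, 142 and 576 with the spike-ins, 131 and 124 with the normexp background, 977 and 1215 without the filter on dim probes, and 118 and 86 among probes above the median signal. At 1.5-fold they were 857 and 1163, and at 3-fold 58 and 53. The log2 bound of Pnpla8, -2.77, was -2.91 with loess, -3.01 without scaling, -2.92 with the spike-ins and -1.10 with normexp; without the filter the value of -4.77 rests on a knockout signal at background (4.45, against a negative-control median of 4.28) and adds nothing to the bound, and among probes above the median signal it had no value. The offset of normexp and the filters draw dim genes toward 0 or remove them by construction. The count of lists outside the random range, 23, ran from 20 to 26. No scaling, the median, the spike-ins and the value table shift every gene by a constant, so they could not change it; with quantile, loess and normexp the same 23 lists stayed outside. Lists inside the range moved outside it by the mean (ATF4, acute phase, neutrophil and patatin-like phospholipase), with outlier-marked spots kept (bile acid, heat shock and pericentral) and with unmatched random lists (fatty acid oxidation and pericentral). Among groups outside the random range, the medians of 5 changed sign: cardiolipin (-0.066), circadian clock (-0.028) and the olfactory receptor symbols (-0.068) without scaling, fetal genes (0.095) without the filter and eicosanoid genes (0.020) among probes above the median signal; beyond the scaling shift the cause was not tested. The medians of 15 lists inside the random range or too small for it also took both signs across settings. Of 103 genes at 2-fold or more that were named or belong to the groups followed, none changed sign under any setting that gave a value. That outcome was all but fixed, because they were chosen for size on the same arrays and the largest shift of all genes was -0.25. Of the 103, 82 kept 2-fold with normexp, 89 without scaling and 93 with the spike-ins. Signal over background limits the dim genes: near the floor, the filter on dim probes decides which are counted.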

Other observations

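The gene groups in this paragraph were chosen after their values were seen. Grouping measured genes by the start of their symbol gave 371 groups of at least 6 genes. Of these groups, 63 had a median outside the middle 95% of random lists, where 18.6 would if members varied independently. Related genes can vary together, so that excess does not measure an effect of genotype. Of the 63, 45 were lower and 18 higher in the knockout pool. The sulfotransferases (Sult) had a median of 0.90 over 13 genes, with 12 above 0 and 6 at least 2-fold higher. Besides Sult1e1, Sult1d1 and Sult2a4, these were Sult2a3 (2.98-fold), Sult2a2 (2.85-fold) and Sult2a6 (2.14-fold), whose probes can bind near-identical copies. Sult2a6 fell short of 2-fold without scaling, with quantile, loess or spike-in scaling and by its brightest probe. The guanylate-binding proteins (Gbp), which interferon induces, had -0.92 over 11 genes, with Gbp2b 3.93-fold lower. All 6 beta-tubulin symbols (Tubb) were below 0, with a median of -0.52, and all 10 coenzyme Q genes (Coq) above 0, with 0.31. The fatty acid-binding proteins had -0.91 over 7 genes, with Fabp7 3.69-fold and Fabp5 3.61-fold lower and Fabp1, the main hepatocyte form, at -0.01. These medians kept their sign under every setting, but that of the fatty acid-binding proteins was -0.38 with normexp and that of the coenzyme Q genes 0.062 without scaling. Of 28 major histocompatibility complex symbols (H2-), 6 were at least 2-fold lower, led by the class II genes H2-Aa (3.21-fold), H2-Eb1 (3.16-fold) and H2-Ab1 (log2 ratio -1.59), and 1, H2-M5, was 2.68-fold higher. H2-Oa, among the lower, and H2-M5 fell short of 2-fold with normexp. The olfactory receptors, 216 symbols above background, had a median of 0.18, which was -0.068 without scaling, on arrays where the negative controls were 0.53 higher in the knockout after scaling.

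Of the tests below, those of cell type dilution, of differences between pools, of fasting and of sex makeup were chosen after the result was seen; those of the signal trend, time of day, glucocorticoid signalling and growth hormone signalling were fixed before the values they measure were seen, though list medians were known.

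Kupffer cell, lymphocyte, interferon and cell cycle genes were lower in the knockout pool, with 96 of 98 measured genes below 0 and a median of -0.86. A trend with signal shared by all genes is argued against, since gene medians over deciles of mean signal ran only from 0.00 to 0.11. Loess on mean signal could remove only a trend of that kind, so it could hardly have lifted these lists. Their median was -0.91 after it (gene-resampling 95% range -0.97 to -0.81, which does not measure differences between pools). The median was -0.67 with normexp and -0.71 over the 53 genes with probes above the median signal. The lymphocyte part is less settled: its median fell from -0.89 to -0.47 with normexp and to -0.14 among the brighter probes. The 5 genes left there (gene-resampling 95% range of the median -1.42 to -0.04) are too few to settle its size. A higher share of hepatocyte RNA, which would lower every other cell type alike, is argued against as the whole explanation. The Kupffer and lymphocyte median lay below that of endothelial, stellate and cholangiocyte markers by a difference of -0.74 (gene-resampling 95% range -0.90 to -0.61). Those types disagreed: stellate (-0.41) and endothelial (-0.16) medians were lower too, and the cholangiocyte median (0.12) was not. A partial dilution is therefore not excluded. A difference between the pools unrelated to genotype cannot be told apart from genotype with 1 array per genotype. Fewer or less active immune cells in the knockout livers may therefore be a hypothesis to test in single animals.

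Amino acid breakdown genes were higher and fatty acid synthesis genes lower. Higher glucocorticoid signalling is a candidate explanation: 13 measured genes known to respond to glucocorticoids, 3 of them also in the fixed lists, had a median of 0.51, above all 10000 random lists, with 12 above 0 and Cebpd (2.07-fold) and Tsc22d3 (2.06-fold) highest. Without scaling the median was 0.26, and both genes fell short of 2-fold there and with quantile, loess or spike-in scaling. A different time of collection stays open. Clock genes of opposite phase differed by 0.62, past the 0.5 set beforehand. That rested on 3 genes against 9, with a resampling range of -0.29 to 0.87. With the main scaling both medians lay above 0, at 0.83 for the 3 genes and 0.21 for the 9. The 2 phases thus differed in size and not in direction. The difference was 0.37 with normexp, 0.39 without the filter on dim probes and 0.31 with outlier-marked spots kept. It was -0.017 among brighter probes, where 1 of the 3 genes was left. A fasted state was not decided. The 12 fasting-induced genes had a median of 0.28 (range -0.04 to 0.50), between the 0.5 set for it and the 0.2 set against it, and Fgf21 was lower. That median fell below 0.2, on the side set against fasting, with quantile (0.197), loess (0.195) or spike-in scaling (0.13) and without scaling (0.034). These states could also act together, and none was separated from genotype.

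Male-biased genes were lower and female-biased genes higher. A different sex makeup of the pools is argued against, since no sex chromosome probe was above background on 1 array only and the largest log2 ratio of an Xist probe was 0.15 in size. Xist was well above background in both pools and no Y-linked probe was in either, so both pools read as female by these probes. No array of known male RNA was at hand to check the Y-linked probes. Lower growth hormone signalling stays open: the median over Igf1, Igfals, Socs2 and Cish was -0.505, barely past the -0.5 set beforehand, with single values from -0.85 to -0.21, and it fell short of -0.5 with median scaling (-0.48), with normexp (-0.49) and with the mean of probes per gene. The 4 genes are few and the growth hormone list as a whole was inside the random range, so this may not hold in other pools.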
